A study of Homo sapiens with 12 samples.

How the data were processed

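Chromatin from Raji, Namalwa and L428-PAX5 cells was fixed with 1% formaldehyde for 20 min and precipitated with 10 µg of an antibody against PAX5, and 50 µl of chromatin was kept as input, per the labels' protocols. There were 2 immunoprecipitated and 2 input libraries for each line, 12 samples in all. Groups were taken from the sample titles, which give the line, the replicate number and whether the library was immunoprecipitated or input. The labels do not say whether the libraries of a line came from separate cultures.

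The authors deposited a peak list for each of the 6 immunoprecipitated libraries, and the lists were thus called per library and not on pooled reads. The submitters' processing notes name CASAVA 1.3 and 1.8, BWA 0.5.9-r16 and the genome build hg19. Each deposited list gives chromosome, start, end, a peak name and a p-value per peak, whose unit was read from the values. All p-values lie below 1e-05, and the peak names carry the name PeakRanger, a peak caller, and are numbered without a gap. The settings and version of the caller, whether the input served as its control, whether the value is a p-value or an adjusted one, and whether starts count from 0 or from 1 are not given in the sources used here. The 6 input libraries were not analysed here, so no background level from input stands beside the peaks. Read depth per library is unknown. A peak list moves with depth and with the yield of the precipitation, and a region absent from a list can lie below its threshold.

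From the lists, peaks of all libraries were merged into regions where they overlapped by at least 1 bp or touched, through chains of peaks where needed. A region was reproducible in a line when both libraries of the line had a peak in it. The Jaccard index of 2 libraries was the number of regions with peaks of both divided by the number with a peak of either. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error over peaks or regions only. Chance overlap came from 1000 random circular shifts of 1 list along each chromosome, with a one-sided permutation p. The shifts can place peaks anywhere on a chromosome, also where no peak can be called. Lists that only favour the same kind of sequence would exceed them too, so the p does not show that shared sites are specific to PAX5. The mean index over Raji and Namalwa pairs minus the mean over pairs of a B-cell line with L428-PAX5 was tested by exact permutation over the 15 choices of 2 libraries out of 6, with pairs of 1 line left out of both means. The strength of a region was the mean, over libraries, of the percentile of its p-value within each list, and strengths of found and not found regions were compared by a two-sided permutation test with 100000 resamples. The p-values of the authors were used to describe, rank and filter peaks within a list. The chromosome end was taken as the largest peak end on that chromosome in any list, since no sequence lengths of hg19 were at hand.

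Regions were named by a rule fixed before the data were examined: the 10 top regions by mean within-list percentile among those in all 6 libraries, among those in both B-cell lines and neither L428-PAX5 library, and among those in both L428-PAX5 libraries and no B-cell-line library. A planned assignment of regions to genes, with gene lists, genomic position and a search for the PAX5 motif, was not run, because the gene table at hand is on GRCh38.p14 while the lists are on hg19 and no genome sequence of hg19 was used here. Coordinates were not converted between builds.

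The tests, the main overlap rule and the alternatives were fixed before the data were examined. The alternatives were a reciprocal overlap of 50%, peak centres within 200 bp, the better 50% of each list by p-value, lists cut to the 2107 best peaks, each library left out in turn and pairs of libraries with the same replicate number only. Added after seeing the data were the omission of peaks on unplaced contigs, the use of peak centres, of the better 50% and of equal-length lists in the strength test, the comparison of directions, chromosomes and single strongest regions, and the distance and list settings for positions near chromosome ends. The scripts were tested on simulated lists. With 24% of 1200 simulated B-cell-line regions placed in L428-PAX5, 24.2% were recovered, and 1 of 15 pairs of unrelated lists had a shift p of 0.05 or less. Each simulated region was placed in both libraries of its lines, with no peak missed. The recovery thus checks the counting only, and not how peaks missed in the real lists move the share. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.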

Results

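PAX5, the transcription factor that sets and keeps B-cell identity, was mapped by chromatin immunoprecipitation and sequencing in 3 human lymphoma cell lines. Raji and Namalwa are lines from Burkitt lymphoma, a tumour of mature B cells, and are called the B-cell lines here. L428-PAX5 derives from L428, a line of classical Hodgkin lymphoma, whose tumour cells come from B cells but have lost much of the B-cell programme. In L428-PAX5 the overproduction of PAX5 was switched on 48 h before fixation. Each line had 2 immunoprecipitated and 2 input libraries, 12 samples in all. The authors' peak lists of the 6 immunoprecipitated libraries, 1 list per library, are what is described below, and read depths are not given in the sources used here.

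The number of PAX5 peaks differed more between the libraries of a line than between lines. The lists held 2619 and 4960 peaks in Raji, 6241 and 2107 in Namalwa and 6201 and 3252 in L428-PAX5, in the order of replicates 1 and 2. The line means were 3789.5 ± 1655 (SD, n = 2) in Raji, 4174 ± 2923 (SD, n = 2) in Namalwa and 4726.5 ± 2085 (SD, n = 2) in L428-PAX5, so that L428-PAX5 did not stand apart from the B-cell lines in the number of peaks. Within a line the longer list held between 1.89 and 2.96 times as many peaks as the shorter one. Peaks covered from 1.13 Mb (Namalwa 2) to 3.76 Mb (Namalwa 1), and the median peak width lay between 461 and 545 bp in every list. The lists were therefore compared both as deposited and after each was reduced to its 2107 best peaks, the length of the shortest list.

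The first question was how far the libraries of a line found the same PAX5 sites. Most peaks of the shorter list of a line were present in the longer one. In Raji, 84.2% of the peaks of replicate 1 overlapped a peak of replicate 2 (exact 95% interval 82.8 to 85.6%). In Namalwa, 90.4% of the peaks of replicate 2 overlapped a peak of replicate 1 (89.0 to 91.6%), and in L428-PAX5, 77.4% of the peaks of replicate 2 overlapped a peak of replicate 1 (75.9 to 78.8%). In the other direction the shares were 44.6% in Raji, 30.8% in Namalwa and 40.7% in L428-PAX5. The Jaccard index, the number of merged regions found in both libraries divided by the number found in either, was 0.410 for Raji, 0.296 for Namalwa and 0.361 for L428-PAX5. With lists of equal length it was 0.512, 0.490 and 0.445. Counted over covered bases of the lists as deposited, as was planned, the index was 0.336 for Raji, 0.234 for Namalwa and 0.308 for L428-PAX5. Random shifts of 1 list along the chromosomes gave at least 269-fold fewer overlapping peaks (one-sided permutation p = 0.000999 for each line, the smallest value that 1000 shifts allow). The share found in the other library rested on list length, and with equal lengths it lay between 61.7 and 67.8% in all 6 libraries.

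The central comparison was between the PAX5 sites of the B-cell lines and those of L428-PAX5. Raji and Namalwa shared many sites with each other and few with L428-PAX5. The Jaccard index averaged 0.277 ± 0.039 (SD over 4 pairs of libraries) between Raji and Namalwa, with a range of 0.242 to 0.330. Between a B-cell line and L428-PAX5 it averaged 0.0552 ± 0.0104 (SD over 8 pairs), with a range of 0.0441 to 0.0709, so that no pair with L428-PAX5 came near the lowest pair of the B-cell lines. With lists of equal length the means were 0.303 ± 0.011 and 0.0446 ± 0.0062, and the gap between them was 0.258. The shared sites of L428-PAX5 and the B-cell lines were still 45.8 to 82.7 times as many as random shifts gave (one-sided permutation p = 0.000999 for each of the 8 pairs).

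In the lists as deposited the 2 mean indices differed by 0.222. Among the 15 ways of choosing 2 of the 6 libraries as the L428-PAX5 pair, the true choice gave the largest difference, and the highest of the others was 0.0356 (one-sided exact permutation p = 0.0667). This is the smallest p that 15 choices allow, so the design cannot reach 0.05. Most of the 15 choices also place the 2 libraries of a line on different sides, unlike the true choice. They are thus no fair comparison for it, and the p cannot serve as evidence for the gap. The gap is described by the mean indices and their ranges only. The libraries are labelled only by line and number, so the spread between libraries of a line may be technical. L428-PAX5 is the only Hodgkin line here, and the p-value says nothing about the spread between lines of a kind.

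**Figure D1:**
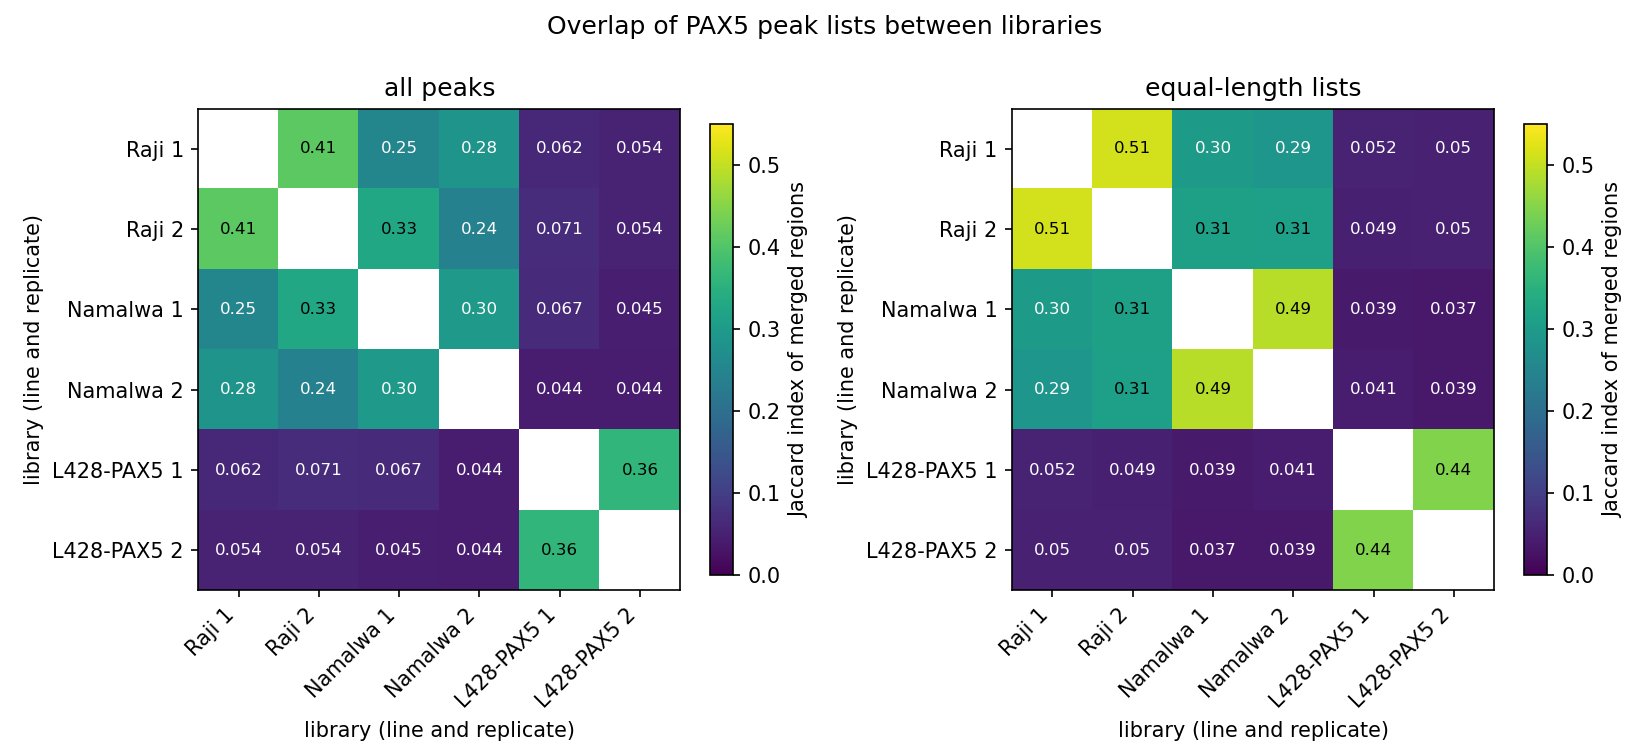
Jaccard index of merged PAX5 regions for each pair of the 6 libraries (axes: line and replicate; colour and printed value: index), for all peaks (left) and for the 2107 best peaks of each list (right). Pairs of a B-cell line with L428-PAX5 lie between 0.0441 and 0.0709 on the left, and pairs of Raji with Namalwa between 0.242 and 0.330.

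Merging all peaks that overlapped or touched gave 14465 regions, of which 7967 (55.1%) were found in 1 library and 147 (1.02%) in all 6. A region was taken as reproducible in a line when both its libraries had a peak there, which held for 5305 regions in at least 1 line. Raji had 2179 reproducible regions, Namalwa 1879 and L428-PAX5 2487. The regions reproducible in both B-cell lines numbered 966, made up of the 147 found in all 6 libraries and 819 that were not reproducible in L428-PAX5. A further 92 were reproducible in Raji and L428-PAX5 and 35 in Namalwa and L428-PAX5. L428-PAX5 alone had 2213 reproducible regions, against 1121 in Raji alone and 878 in Namalwa alone.

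**Figure D2:**
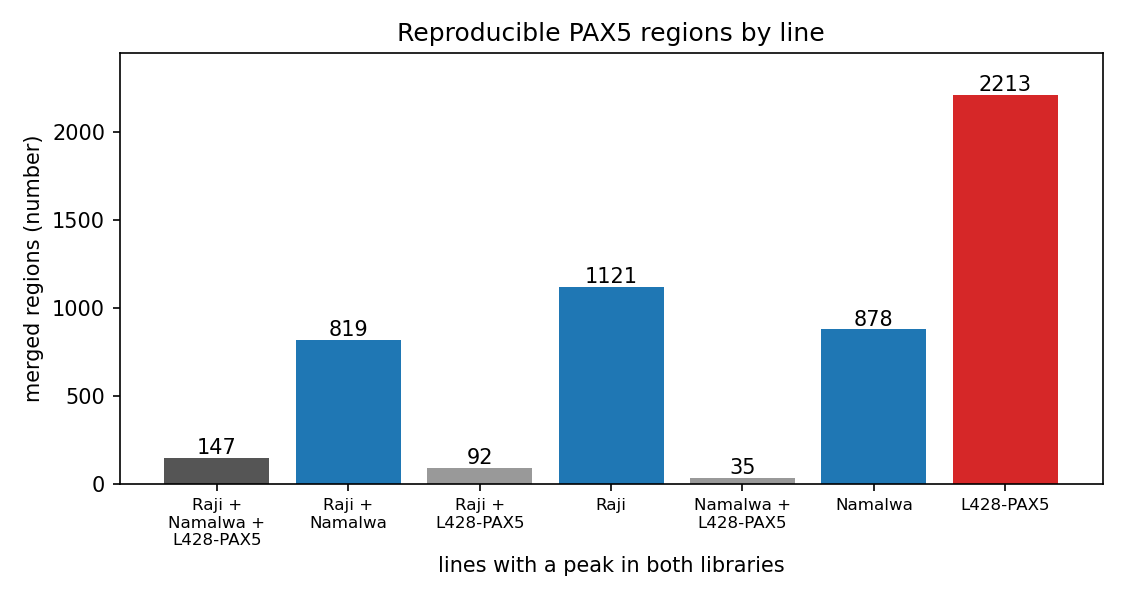
Number of merged PAX5 regions (y axis) by the lines in which both libraries had a peak (x axis). L428-PAX5 alone had 2213 regions and all 3 lines together 147.

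Most PAX5 sites common to Raji and Namalwa had no peak in L428-PAX5. Of the 966 regions of both B-cell lines, 271 (28.1%, exact 95% interval 25.2 to 31.0%) had a peak in at least 1 L428-PAX5 library and 147 (15.2%, 13.0 to 17.6%) in both, and 695 had none in either. Shifted L428-PAX5 lists met on average 3.69 of the 966 regions and at most 11, so the observed number was 73.4 times the mean of the shifts (one-sided permutation p = 0.000999, the smallest possible). Shifts along whole chromosomes set a low bar for overlap. The B-cell lines covered each other far better: 75.8% of the regions reproducible in Raji (73.9 to 77.6%) had a peak in a Namalwa library, and 70.9% of those in Namalwa (68.8 to 72.9%) had one in a Raji library. In L428-PAX5 the same regions were found at 22.6% for Raji (20.8 to 24.4%) and 19.3% for Namalwa (17.5 to 21.1%). Conversely, 2043 of the 2487 L428-PAX5 regions had no peak in any B-cell-line library, and 444 (17.9%, 16.4 to 19.4%) had one. The intervals cover counting error over regions only.

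These counts moved with single libraries, in part by construction. With a library left out, fewer libraries must hold or lack a region, so the counts tend to rise. With a single L428-PAX5 library left, a peak in any and a peak in all of them mean the same. Without Namalwa replicate 2, the shortest list, 1624 regions were common to the B-cell lines and 1226 of these had no L428-PAX5 peak. Without L428-PAX5 replicate 2, 252 regions were found in all libraries, 26.1% of the B-cell-line regions were found in all of L428-PAX5, and 5116 regions were in L428-PAX5 and no B-cell-line library. Without L428-PAX5 replicate 1, the share with any L428-PAX5 peak was 17.1%. With equal-length lists 72 regions were in all 6 libraries and 1100 in L428-PAX5 only, and with the better part of each list by p-value (50% of its peaks) the numbers were 57 and 1091, with 475 regions common to the B-cell lines, 359 of them with no L428-PAX5 peak.

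Single regions are named by position on hg19, with start and end as the peak lists give them (whether the start counts from 0 or from 1 is not stated in them). Gene, exon and intron are not given here, because the annotation at hand belongs to another build. Among the regions found in all 6 libraries, the top one by mean within-list percentile was chromosome 3, 126793570 to 126794552, with a −log10 p of 53.99 to 115.5 in the 4 B-cell-line libraries (mean 90.4 ± 26.0, SD, n = 4) and of 56.4 and 64.7 in L428-PAX5. It was the strongest region of both Raji lists. Next came chromosome 2, 47951216 to 47952232 (75.2 ± 27.0, SD, n = 4, in the B-cell lines and 39.95 ± 6.16, SD, n = 2, in L428-PAX5) and chromosome 9, 131418815 to 131419557 (44.4 ± 20.0 and 18.8 ± 2.6). The other 7 of the top 10 lay on chromosomes 8 (101965089 to 101965989), 22 (33695402 to 33696293), 1 (155214076 to 155214939), X (40028843 to 40029545), 7 (41295 to 42157), 2 (38834765 to 38835419) and 11 (118972181 to 118973120). Over all 10, the −log10 p spanned 15.2 to 115.5 in the B-cell lines and 10.4 to 64.7 in L428-PAX5. A −log10 p moves with the depth of its library, so it ranks peaks within a list and does not measure a change between lines.

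The top 10 regions with a peak in all 4 B-cell-line libraries and none in L428-PAX5 were chosen by rank, so their high ranks follow from the choice. The top one was chromosome 7, 98270937 to 98271781, with a −log10 p of 65.6 ± 21.9 (SD, n = 4) and a mean percentile of 99.8. It was followed by chromosome 1, 31227458 to 31228006 (60.4 ± 18.1, SD, n = 4), chromosome 10, 5882137 to 5883226 (61.0 ± 22.7), and chromosome 6, 107150059 to 107150847 (53.9 ± 17.9). The remaining 6 of the top 10 lay on chromosomes 10 (94516798 to 94517493), 3 (46580191 to 46580968 and 194412351 to 194413106), 14 (25601803 to 25602464), 4 (300242 to 300889) and 13 (41163432 to 41164266). Over the 10 regions the values ran from 20.8 to 95.7, and the lowest mean percentile was 98.3.

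The top 10 regions found in both L428-PAX5 libraries and in none of the 4 B-cell-line libraries, chosen by rank, were also among the strongest of their lists. No filter for repeats or copy number was applied and input was not examined, so such peaks may have sources other than PAX5. The top one was chromosome 5, 3282786 to 3283576, with a −log10 p of 155.8 and 123.5 in replicates 1 and 2. Chromosome 14, 106048910 to 106049513, had 133.0 and 115.0, and chromosome 2, 44513466 to 44514200, had 107.7 and 80.8. The other 7 of the top 10 lay on chromosomes 10 (13515295 to 13516935), 2 (241137068 to 241138409), 7 (156733491 to 156734790 and 154958354 to 154958889), 17 (25264224 to 25265580 and 3698865 to 3699528) and 22 (20760238 to 20761208). All 10 had values of 51.2 or more in both libraries.

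A further question was whether the strength of a site in the B-cell lines went with its presence in L428-PAX5. The stronger B-cell-line regions were found in L428-PAX5 more often, yet most of the strongest were not found. The regions were split into 4 strength classes of equal size by mean within-list percentile. From the weakest to the strongest class, 21.9%, 22.4%, 28.6% and 39.3% (exact 95% interval of the strongest class 33.1 to 45.7%) of the B-cell-line regions had a peak in any L428-PAX5 library. For peaks in both L428-PAX5 libraries the shares were 7.44%, 11.2%, 19.1% and 23.1%. The 271 regions found had a mean percentile of 75.9 ± 17.6 (SD) and the 695 not found 70.3 ± 17.5, a difference of 5.65 (two-sided permutation test, 100000 resamples, p = 3e-05). Regions are not independent replicates, and the test describes these lists.

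In every strength class the B-cell lines found more of each other's regions than L428-PAX5 did. Of the regions reproducible in Raji, 60% of the weakest class and 92.7% of the strongest (90.1 to 94.7%) had a peak in Namalwa, while 16.9% and 34.1% had one in L428-PAX5. Of the regions reproducible in Namalwa, 53.6% of the weakest and 88.1% of the strongest class (84.8 to 90.9%) had a peak in Raji, and 13.2% and 28.3% had one in L428-PAX5. The strongest class of the L428-PAX5 regions was found at 16.2% in Raji (13.4 to 19.4%) and 15.8% in Namalwa (13.0 to 18.9%), against 13.7% (11.1 to 16.6%) and 15.1% (12.4 to 18.2%) of the weakest, and these intervals overlap.

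**Figure D3:**
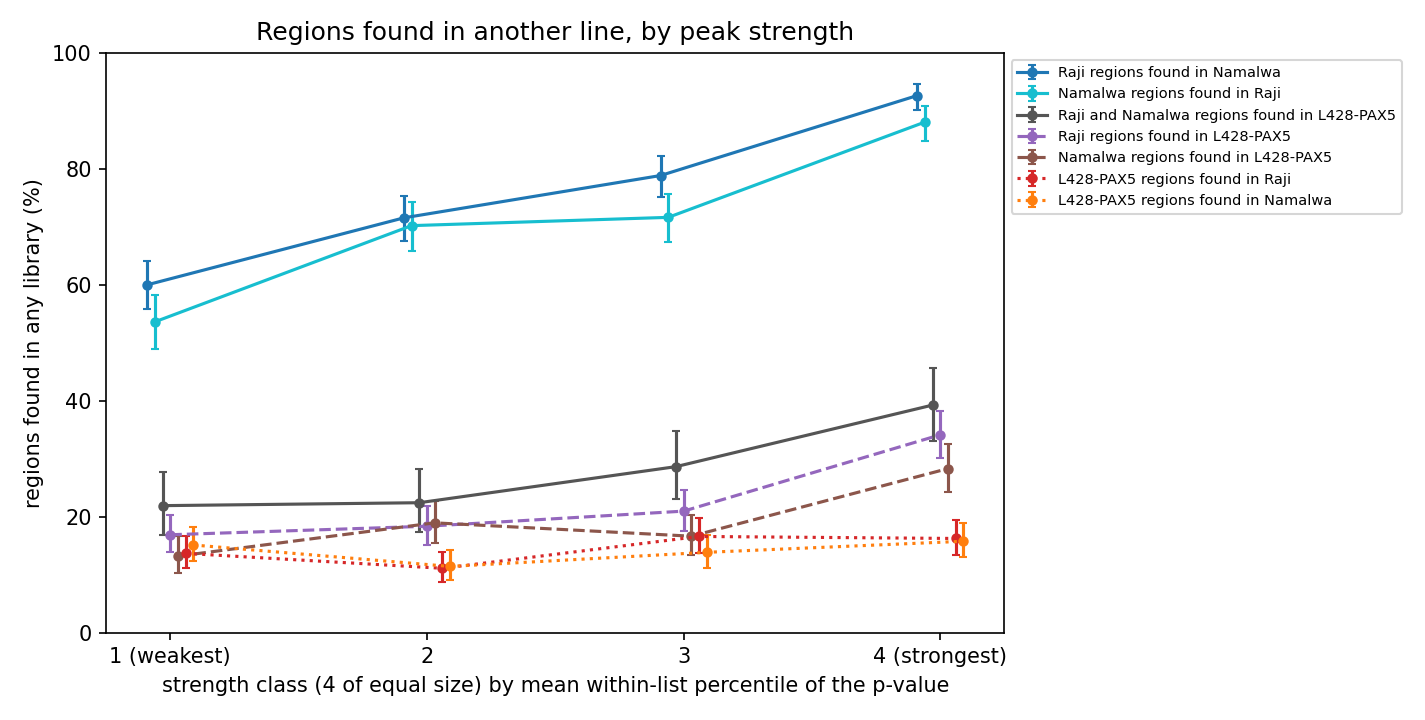
Share of reproducible regions with a peak in any library of another line (y axis, %, bars: exact 95% intervals) by strength class, 4 classes of equal size by mean within-list percentile of the p-value (x axis). In the strongest class 92.7% of Raji regions were found in Namalwa and 34.1% in L428-PAX5, and 16.2% of L428-PAX5 regions were found in Raji.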

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

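The comparison below was chosen after the results were seen. Strength went with presence in another line to a different degree in the 2 directions between L428-PAX5 and the B-cell lines. Raji regions found in L428-PAX5 had a mean percentile 8.37 above those not found, while L428-PAX5 regions found in Raji lay 2.84 above those not found, and the gap between these differences was 5.52 (permutation p = 0.0027, 10000 permutations of found and not found). For Namalwa the differences were 7.11 and 0.968, with a gap of 6.14 (permutation p = 0.0012). Between Raji and Namalwa the differences were 15.6 and 13.2, with a gap of 2.42 (permutation p = 0.137). After Benjamini-Hochberg adjustment over the 6 directions, each of the 4 that start from a B-cell line had a permutation p of 0.00015, L428-PAX5 to Raji had 0.047 and L428-PAX5 to Namalwa 0.475. The permutations take strength and presence as unrelated in both directions, which the adjusted values of the directions from a B-cell line go against. The p-values of the gaps thus do not test whether the 2 directions are equal. Regions are not independent replicates, and the gaps describe these 6 lists.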

How the results depend on the processing

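The settings for peaks on unplaced contigs, and for the strength test all but the reciprocal overlap and the left-out libraries, were chosen after seeing the data. Of 152 values recomputed, 48 moved beyond the SD over pairs of libraries, the interval or 1.5 times the count. The strength difference, the difference between the mean indices and that near chromosome ends were judged by direction or p only. They could thus not count as moved. Some values hardly change by construction, such as the Raji and Namalwa index without an L428-PAX5 library. The strength difference kept its direction and a permutation p under 0.05 in all 7 of its alternatives. The difference between the mean Jaccard indices (12 alternatives) and that near chromosome ends (8 alternatives) kept their direction, but their exact tests cannot pass 0.05 under any setting, so nothing follows for their calls. In the order Raji 1, Raji 2, Namalwa 1, Namalwa 2, L428-PAX5 1 and L428-PAX5 2, the shares of peaks found in the other library were 78.7, 41.5, 27.7, 82.1, 37.5 and 71.6% with a reciprocal overlap of 50%, 78.9, 41.7, 27.9, 82.6, 37.2 and 71.0% with centres within 200 bp, and 67.8, 67.7, 65.9, 66.1, 61.7 and 61.7% in equal-length lists. In the better part of each list they were 85.6% for Raji 1, 91.9% for Namalwa 2 and 78.8% for L428-PAX5 2. The mean index with L428-PAX5 was 0.0439 in the better part and 0.0446 in equal-length lists.

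In the better part of each list, 475 regions were common to the B-cell lines, 57 in all libraries, 359 without an L428-PAX5 peak and 1091 in L428-PAX5 only, and 24.4% and 12% of the common regions were found in any and in both L428-PAX5 libraries. Fewer peaks enter there by construction. In equal-length lists 72 regions were in all libraries and 1100 in L428-PAX5 only, and the shares were 19.1% and 10.5%. Leaving out each library in turn gave 966 to 1624 common regions (highest without Namalwa replicate 2), 149 to 252 in all libraries (highest without L428-PAX5 replicate 2), 714 to 1226 without an L428-PAX5 peak (highest without Namalwa replicate 2), and 2046 to 5116 in L428-PAX5 only (highest without L428-PAX5 replicate 2). The shares then ran from 17.1% (without L428-PAX5 replicate 1) to 28.1% for any and from 12.5% to 26.1% (without L428-PAX5 replicate 2) for all L428-PAX5 libraries. Leaving out a library loosens the rule, since fewer libraries must hold or lack a region, so higher counts arise in part by construction.

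With the replicate number as a block, comparing same-numbered libraries only, the mean indices differed by 0.190 (one-sided exact permutation p = 0.111). Most choices of this test split lines too, so its p is no evidence for the gap either. Averaged over the numbers 1 and 2, there were then 1560 common regions, 297.5 in all libraries, 1262.5 without an L428-PAX5 peak and 4023.5 in L428-PAX5 only, and 18.5% of common regions had an L428-PAX5 peak. Fewer libraries must hold a region under the block. The numbers were not treated as pairs: same-numbered and other pairs had mean indices of 0.247 and 0.307 between Raji and Namalwa, and 0.0567 and 0.0537 with L428-PAX5. The planned swap of the ranking score was not run, since each list holds 1 score, and the alternatives for gene lists, genomic position and motif were not run, since their main values were not computed. Depth was not known, so a missing peak is not a measured absence.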

Other observations

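The tests of the detection threshold, of noise, of a preference for chromosome ends and of list length, and all descriptions of single regions and autosomes here, were chosen after the results were seen. The strongest region was the same in both libraries of each line. In Raji it was the region on chromosome 3 that all 6 libraries share. In Namalwa it was chromosome 2, 239684938 to 239686530, with a −log10 p of 158.8 and 117.9, and no peak in Raji or L428-PAX5. In L428-PAX5 it was chromosome 2, 240513807 to 240515751, with 220.3 and 169.2, and of the 4 B-cell-line libraries only Namalwa 1 had a peak there, with 11.6. Windows of 100 kb with 3 or more regions held 6.61% of the L428-PAX5-only regions and 2.01% of the B-cell-line regions without an L428-PAX5 peak, while random samples of the first set, as large as the second, gave 1.27% (0 to 2.74% over 1000 draws).

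Each line spread its peaks over the chromosomes in its own way. Both L428-PAX5 lists had a larger share of peaks than all 4 B-cell-line lists on 6 of 22 autosomes (2, 6, 8, 9, 12 and 17) and a smaller share on 7 (1, 10, 11, 13, 14, 18 and 22). Random order of 6 unrelated libraries would give 13.3% of autosomes. The 2 libraries of a line resemble each other, so that share is no fair comparison, and no excess over chance follows. Chromosome 13 held 1.16% of the L428-PAX5 peaks and 2.78% of the B-cell-line peaks, chromosome 17 held 6.23% and 3.96%, and chromosome 9 held 5.11% and 3.31%. The Namalwa lists stood apart from the other 4 on 9 autosomes and the Raji lists on 6, while no pair of libraries from different lines did so on more than 3.

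Most regions of both B-cell lines were missing from the L428-PAX5 lists, and 3 technical explanations were tested. If weak peaks fell below the threshold in L428-PAX5 and nothing else differed, the strongest strength class should be found as often as between the B-cell lines. Of that class 39.3% was found, with an upper limit of 45.7%, against a lower limit of 84.8% for Namalwa in Raji. This argues against a threshold as the only cause. A threshold also predicts the rise from 21.9% in the weakest class. The median −log10 p was lowest in L428-PAX5 (7.38 and 7.05, against 7.54 to 8.62 in the B-cell lines). It moves with depth, and Raji 1 (7.54) and Namalwa 2 (7.55) lay close, so the medians do not show a stricter threshold in L428-PAX5. A part played by the threshold thus stays open. If the L428-PAX5 lists were mostly noise, they should overlap each other little, but their Jaccard index at equal length was 0.445, near the 0.490 of Namalwa and far from the highest value with a B-cell line, 0.0524. Loss or gain of whole chromosomes would leave some chromosome with shares as high as between the B-cell lines, but among the 21 chromosomes with 20 or more regions the highest share, on chromosome 16, was 43.9% (28.5 to 60.3%, 41 regions) against 75.8%, while chromosome X, with 55.6% of 9 regions (21.2 to 86.3%), had too few to tell. The pattern may reflect a different choice of sites by PAX5 in L428-PAX5, as a hypothesis that was not tested. L428-PAX5 differs from the B-cell lines in line, tumour type and induced overproduction of PAX5 together, so these cannot be told apart. Peaks that recur in a line for reasons other than PAX5, which the input libraries would show, were not tested either.

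The spread over autosomes may come from copy number, which raises the number of peaks that pass on a gained chromosome. If so, autosomes with an excess of L428-PAX5-only regions should also show more of the B-cell-line regions in L428-PAX5. Over the 22 autosomes Spearman's rho was 0.32 (permutation p = 0.145, bootstrap 95% interval −0.116 to 0.667) and Pearson's r 0.363 (permutation p = 0.098), and r was 0.243 without chromosomes 13 and 9. This was the 1 relation computed, and its interval leaves copy number and a line's own choice of sites open, so they cannot be told apart here. List length is argued against, since in equal-length lists the L428-PAX5 lists still stood apart on 13 of 22 autosomes, while no 2 libraries from different lines did so on more than 3.

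A hypothesis was that L428-PAX5 peaks lie near chromosome ends more often, and within 5 Mb of an end lay 12.8 ± 1.1% (SD, n = 2) of L428-PAX5 peaks and 10.8 ± 2.4% (SD, n = 4) of B-cell-line peaks (one-sided exact permutation p = 0.2, smallest possible 0.0667), with the lower L428-PAX5 share, 12%, below the 13.8% of Namalwa 2. By library these 5 Mb shares were 9.16 and 8.57% in Raji, 11.7 and 13.8% in Namalwa and 13.6 and 12.0% in L428-PAX5. L428-PAX5 and Namalwa thus overlapped there, and Raji lay lower. The mean was higher in L428-PAX5 than over the 2 B-cell lines pooled in all 9 settings of distance and list, by 1.08 to 5.60 percentage points. Both L428-PAX5 lists lay above all 4 B-cell-line lists in only 1 of these settings, the better part of each list at 10 Mb (lowest 23.2% against highest 22.7%, one-sided exact permutation p = 0.0667). Of the L428-PAX5-only regions, 23.7% (21.9 to 25.6%) lay within 10 Mb of an end and 13.2% (11.7 to 14.7%) within 5 Mb, against 16.8% (14.1 to 19.8%) and 9.93% (7.81 to 12.4%) of the B-cell-line regions without an L428-PAX5 peak, while the regions of all 6 libraries had 23.6% (16.9 to 31.4%) and 12.5% (7.58 to 19.0%). Weak peaks of the longer lists were tested by the lower L428-PAX5 share within 5 Mb in equal-length lists, 12.3%, which decides nothing because the full lists already overlapped, and the mean difference there was 3.39 percentage points against 2.0 in the full lists, where weak peaks predict a smaller one, though the change is within the SDs. Of 34 chromosome ends with 20 or more regions, 50% (32.4 to 67.6%) had a larger L428-PAX5-only share than the rest of their chromosome. That is also what no pattern would give, so the count shows no general excess at ends. It cannot tell copy gain of single ends from a preference for ends.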
